A study of Nicotiana tabacum with 6 samples.

How the data were processed

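RNA-seq libraries, 6 in number, came from tobacco BY-2 cells, a fast-dividing suspension line of Nicotiana tabacum cultivar Bright Yellow 2 that grows in the dark on medium containing the synthetic auxin 2,4-D. The line carried an Arabidopsis PIN5 transgene (AtPIN5) under estradiol control. Cells had received 1 µM β-estradiol in DMSO (group EST, 3 libraries) or DMSO alone (group DMSO, 3 libraries) for 48 h, as given in the labels. The labels number both groups as biological replicates 1 to 3. They also name the company that sequenced each library: Novogene for all 3 DMSO libraries and for EST replicate 1, and IAB for EST replicates 2 and 3. The library identifiers in the sample titles run close together for DMSO 1 with EST 1, for DMSO 2 with DMSO 3 and for EST 2 with EST 3.

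Reads were trimmed with Trimmomatic and quantified with Salmon 1.3.0, per the submitters' processing notes. The version of Trimmomatic, the Salmon options and the read layout are not given in the sources used here. Each deposited file gives, per index entry, an estimated count of reads, a TPM value (transcript abundance corrected for effective length and library size) and an effective length. All 6 files list the same 69492 entries: 69491 gene models of the Nitab4.5 annotation, each with 1 transcript entry, and 1 entry for AtPIN5. The estimated counts deposited by the authors are not normalized and are not whole where Salmon divides reads between similar entries. Tobacco is an allotetraploid, so near-identical gene copies are common, and between 39.3% and 56.3% of the detected entries of a library had an estimate more than 0.0015 reads from a whole number. Levels of single gene models that share reads are therefore uncertain. The TPM values deposited by the authors have the same sum in each library and depend on the effective length, another deposited column (in bases), which differs between libraries for the same entry.

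The files pair no gene names with the Nitab4.5 identifiers, and 0 of the 69491 identifiers matched the reference gene table at hand (tobacco K326 assembly ASM71507v2). The 36 gene lists fixed in advance, which select genes by their descriptions, could therefore not be applied, and no list or gene set result is given. Genomic coordinates are not used here for the same reason.

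Estimated counts were rounded to whole numbers. Entries were kept by filterByExpr of edgeR 4.0.16 (R 4.3.3) with its defaults of 10 counts and 15 in total, which left 33956 entries. Libraries were scaled by TMM, and edgeR's quasi-likelihood test with robust dispersion and Benjamini-Hochberg adjustment was applied at an adjusted p of 0.05. The company-adjusted fit used all 6 libraries with company as a covariate, so its treatment term compares EST 1 with the 3 DMSO libraries and takes the spread from the DMSO libraries and from EST 2 and 3. The pooled fit had no company term. A further count took the entries called in both fits with the same sign whose 3 EST libraries lay all above or all below the 3 DMSO libraries. Standard errors were taken from the fold change and its F statistic. Log2 CPM values (counts scaled to library size) for correlations and principal components used a prior count of 2.

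The rule for named genes was set before the data were examined: AtPIN5, and, because no descriptions pair with the identifiers, the 2 entries with the largest rise and the 2 with the largest fall in the company-adjusted fit among those called in both fits with a mean of at least 10 counts in the higher group. One further entry, named where it is the only call left, was chosen after its values were seen.

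Total estimated reads ranged from 11776234 (EST 1) to 17281241 (EST 2). For entries with 0 reads in a whole group, the floor was set at 3 counts over the group. Count ratios carry exact Clopper-Pearson 95% intervals, and these intervals and floors cover counting error only. Where the labels do not say how separate the cultures were, p-values measure the spread between these libraries, which may in part be technical.

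Replicate numbers are shared between the groups. Deviations of log2 CPM from the group means correlated at 0.39 for replicate 1, 0.13 for replicate 2 and 0.33 for replicate 3. All 3 lie over the 0.1 set as the criterion for pairing, so the replicate number was also fitted as a block. The deviations are centred within each group and DMSO 2 and 3 lie close together, so the positive values for replicates 2 and 3, and for DMSO 2 with EST 3 (0.33), follow from that of replicate 1 and are no evidence of pairing.

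The test was tried on simulated counts for the 33956 entries, with 200 of them changed and no company difference. The company-adjusted fit recovered 1.49% of the 2-fold, 37.3% of the 4-fold and 71.2% of the 8-fold changes, with 3 false calls. The pooled fit recovered 14.9%, 85.1% and 93.9%, with 8 false calls. With a 4-fold company difference added to 2000 other entries, false calls were 1 in the company-adjusted fit and 196 in the pooled fit. The simulated libraries were drawn independently, without close pairs such as DMSO 2 and 3, and with far fewer changed entries than were called here. Recovery and false calls in the real data may therefore differ from these values.

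Alternatives set before the data were examined were DESeq2 size factors and upper-quartile scaling within edgeR, no filter and a filter of 10 counts in every library, DESeq2 1.42.0, limma 3.58.1 on log2(TPM + 1), an offset from the effective lengths, the replicate block, the Novogene libraries alone, and each library left out in turn. Added after seeing the data were DMSO 2 and 3 summed into 1 library (with edgeR and with DESeq2), the 3 library pairs as the batch, only entries with whole-number estimates, and removal of each library's trend with transcript length.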

Results

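The transcriptome of a tobacco BY-2 line with an estradiol-inducible Arabidopsis PIN5 gene was measured by RNA-seq in 3 induced (EST) and 3 uninduced (DMSO) libraries of cells 2 days into a subculture interval of 7 days. PIN5 is a member of the PIN family of auxin carriers that resides at the endoplasmic reticulum. The libraries held 16483904, 13136714 and 15165091 estimated reads for DMSO 1, 2 and 3, and 11776234, 17281241 and 14859858 for EST 1, 2 and 3. Between 41022 and 44253 of the 69492 index entries had at least 1 read in a library. The 10 most abundant entries took 2.97% to 3.04% of the reads in the DMSO libraries and 4.73%, 4.89% and 2.68% in EST 1, 2 and 3.

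The first comparison asked whether the transgene was induced. AtPIN5 mRNA was low in every DMSO library and higher in every EST library. It stood at 1.51, 0.387 and 0.942 TPM in DMSO 1, 2 and 3, from 29, 5 and 14 reads, and at 23.99, 95.4 and 341 TPM in EST 1, 2 and 3, from 363, 2009 and 6133 reads. The group means were 0.948 ± 0.563 TPM (SD, n = 3) without and 154 ± 167 TPM (SD, n = 3) with estradiol. Relative to the DMSO mean, AtPIN5 was 25.3-fold higher in EST 1, 100.7-fold in EST 2 and 360-fold in EST 3. In EST 3 the transgene lay above 98.9% of the detected entries, and in DMSO 1, the highest control, above 33.4%.

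AtPIN5 rose by 4.87 ± 0.75 (SE) on the log2 scale in the company-adjusted fit, with an adjusted p of 0.0106 by edgeR's quasi-likelihood test. The pooled fit gave 7.43 ± 1.11 (SE) and an adjusted p of 0.0129. All 3 EST libraries lay above all 3 DMSO libraries, and the two-sided exact permutation test on log2(TPM + 1) gave 0.10, the smallest p that 3 against 3 libraries allow. The pooled call was lost without DMSO 2 (adjusted p = 0.0755) and without DMSO 3 (adjusted p = 0.0791), and the company-adjusted call was kept in all 17 alternatives that could be fitted. Among these, the Novogene libraries alone, the replicate block and the library pairs as batch repeat the contrast of EST 1 with DMSO libraries. They say nothing on stability. AtPIN5 was 3.04 ± 0.92 (SE) log2 units higher in the IAB than in the Novogene EST libraries, which did not pass the threshold in edgeR's test (adjusted p = 0.0994).

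**Figure D1:**
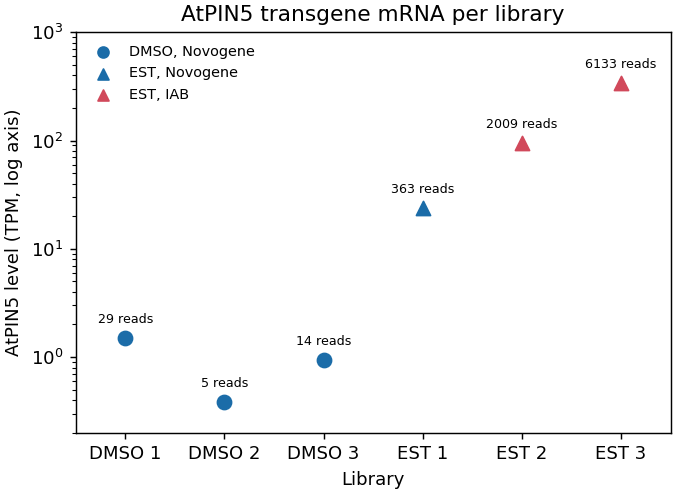
AtPIN5 level in each library (TPM, log axis), with the number of reads behind each point; circles are DMSO and triangles EST libraries, coloured by sequencing company. The 3 EST libraries sit between 23.99 and 341 TPM, all above the DMSO libraries, which sit between 0.387 and 1.51 TPM.

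The second comparison asked which tobacco gene models changed with induction when EST 1 was set against the DMSO libraries of the same company. The company-adjusted fit called 8351 of 33956 gene models (24.6%) at an adjusted p under 0.05 in edgeR's quasi-likelihood test. Of these, 4537 were higher and 3814 lower in EST. This contrast rests on EST 1 as its only induced library within Novogene. Library identifiers and effective-length profiles group EST 1 with DMSO 1 (profile r = 0.43) and apart from DMSO 2 and 3 (r = −0.60 and −0.57). The company term would not remove a batch difference between these Novogene libraries, so such a difference could enter these calls and the AtPIN5 value of the same fit. The count was 16467 without DMSO 1, 2652 without DMSO 2 (1900 higher and 752 lower), 2682 without DMSO 3 (1927 higher and 755 lower), 5408 without EST 2 and 5499 without EST 3.

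The pooled comparison of the 3 EST with the 3 DMSO libraries, which mixes company with treatment, called 3770 gene models by edgeR's quasi-likelihood test, 2695 higher and 1075 lower. With the replicate number as a block, it called 7566, 4487 higher and 3079 lower. There was no evidence of pairing for replicates 2 and 3. DMSO 2 and 3, and EST 2 and 3, lie close together, so these blocks in part repeat 1 contrast and can understate the spread. The higher count is therefore no sign of a gain from pairing. The pooled count was 0 without DMSO 2, where 6711 gene models had an unadjusted p under 0.05, and 1 without DMSO 3. It was 792 without EST 2 and 6771 without EST 1. The single gene model left without DMSO 3, Nitab4.5_0008114g0010.1, which was chosen after its values were seen, held 2, 2 and 0 reads in DMSO 1, 2 and 3 against 437, 1069 and 723 in EST 1, 2 and 3.

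A set of 3053 gene models was called in both fits with the same sign and with no overlap between the groups, 2304 higher and 749 lower in EST. No gene model was called with opposite signs in the 2 fits. Both fits use the same libraries, so the overlap is not independent evidence; lists of these sizes drawn independently would share 360 higher and 121 lower gene models. Groups did not overlap for 36.9% of all tested gene models, where chance gives 10% if the 6 libraries vary independently and 33.3% if DMSO 2 and 3, and EST 2 and 3, each count as 1. The count of 3053 also fell to 0 without DMSO 2, to 1 without DMSO 3 and to 790 without EST 2. With DMSO 2 and 3 summed into 1 library, edgeR left 1 gene model in this set and DESeq2 left 2582.

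Rises outnumbered falls among gene models of low and middle abundance, and falls outnumbered rises among the most abundant ones. In this set, of 17679 gene models with a mean of 1 to 10 TPM over all libraries, 1170 rose and 239 fell, and of 11711 at 10 to 100 TPM, 826 rose and 323 fell. Among 1780 gene models over 100 TPM, 131 rose and 155 fell. The company-adjusted fit alone gave 207 rises and 576 falls in that top class. Falls stayed ahead in the top class under DESeq2 size factors (154 against 133) and under upper-quartile scaling (187 against 117). With DMSO 2 and 3 summed into 1 library the set held 0 falls and 0 rises in the top class, and the company-adjusted fit 148 falls and 80 rises. In the company-adjusted fit the class at 10 to 100 TPM changed its balance with the scaling, from 1706 rises and 1684 falls under TMM to 1504 and 1963 under upper-quartile scaling.

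Some gene models went from no reads to a clear level. There were 68 gene models with 0 reads in all 3 DMSO libraries (44785272 reads together) and at least 1 CPM in each EST library. The reverse held for 5. No other division of the 6 libraries into 3 and 3 gave more than 1 such gene model. Of these, only DMSO 1, EST 2 and EST 3 against DMSO 2, DMSO 3 and EST 1 keeps DMSO 2 with 3 and EST 2 with 3. The rest part libraries that lie close together, so low counts in them were favoured by construction. Against the floor of 3 counts over the DMSO group, the 68 were at least 17.3-fold higher over the EST group, with a median of at least 66.3-fold. Their median level was 5.10 CPM in EST 1, 3.12 CPM in EST 2 and 2.96 CPM in EST 3, and 38 of them stayed under 10 CPM in every library.

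The 4 gene models named by rule were ranked by the company-adjusted fold change, which sets EST 1 against DMSO, so extreme levels in EST 1 are favoured by that choice. Nitab4.5_0000508g0130.1 had 0 reads in all DMSO libraries and 92.1, 3.70 and 13.5 CPM in EST 1, 2 and 3, which is at least 459-fold higher over the EST group than the DMSO group floor. Nitab4.5_0006255g0010.1 had 1 read in the DMSO libraries together and 293, 25.9 and 44.5 CPM in EST 1, 2 and 3, a ratio of 4646 with a counting interval of 833 to 183549. Nitab4.5_0001160g0030.1 fell from 18.8 ± 10.4 CPM (SD, n = 3) in DMSO to 0.475 ± 0.550 CPM (SD, n = 3) in EST, and Nitab4.5_0004122g0030.1 from 9.90 ± 5.63 CPM to 0.815 ± 0.717 CPM (SD, n = 3). Both had 0 reads in EST 1. Their adjusted p values by edgeR's quasi-likelihood test, company-adjusted and pooled, were 0.00622 and 0.0335, 0.000452 and 0.0107, 0.0168 and 0.0177, and 0.0177 and 0.0490, in the order named. None of the 4 had whole-number read estimates in every library, so part of their reads was divided between similar entries. All 4 pooled calls were lost without DMSO 2 and without DMSO 3, with adjusted p values from 0.0706 to 0.180.

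**Figure D2:**
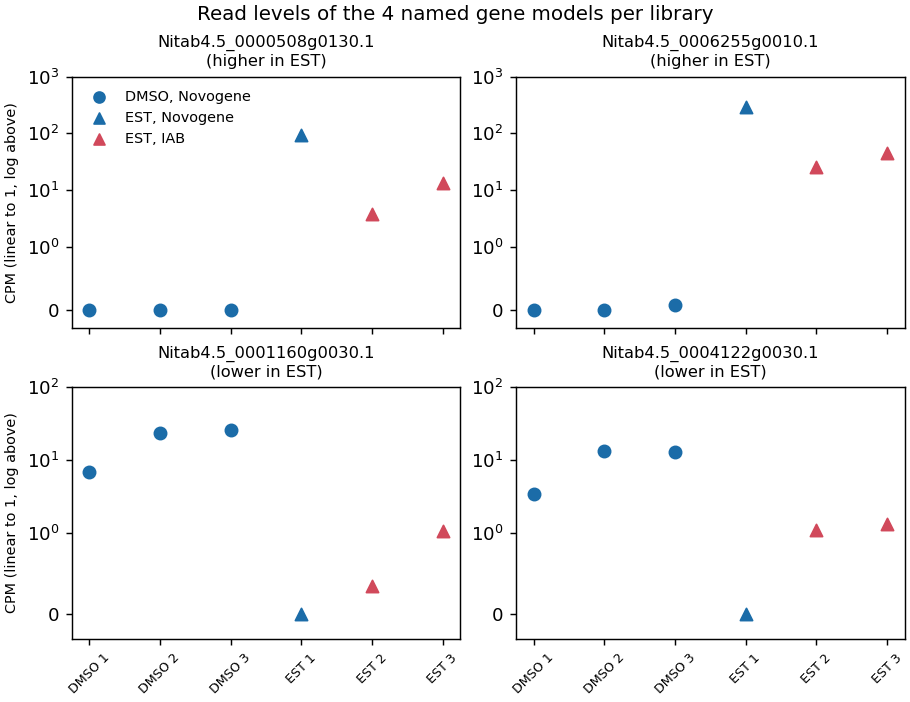
Level of the 4 named gene models in each library (CPM, axis linear to 1 and logarithmic above), circles DMSO and triangles EST, coloured by sequencing company. The first pair is at or near 0 in all DMSO libraries and highest in EST 1, at 92.1 and 293 CPM; the second pair is at 0 in EST 1 and at 0.347 to 1.35 CPM in EST 2 and 3, and the rule that chose them favours extremes in EST 1.

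The response could also be compared between sets of libraries that share no member. Fold changes of EST 1 over DMSO 1 were set against those of EST 2 and 3 over DMSO 2 and 3. Across the 33956 gene models, which are not independent replicates, Pearson's r was 0.65 and Spearman's rho 0.58. Of 5693 gene models that differed by over 2-fold in both sets, 5301 (93.1%) changed in the same direction, 3616 up and 1685 down. The first set lies within 1 company, and the second sets IAB against Novogene libraries. A difference without induction on 1 side also correlated. DMSO 1 minus DMSO 2 gave a Pearson's r of 0.63 with EST 1 minus DMSO 3, 0.50 with EST 2 minus DMSO 3 and 0.45 with EST 3 minus DMSO 3. DMSO 2 and 3 nearly coincide, so both differences subtract nearly the same profile, which favours a positive r by construction. Without that shared profile, DMSO 2 minus DMSO 3 gave 0.0014, −0.017 and −0.013 with EST 1, 2 and 3 minus DMSO 1. DMSO 2 and 3 differ too little for these values to decide either. The r of 0.65 between the 2 sets therefore has no control without induction, and does not by itself show a response to estradiol.

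**Figure D3:**
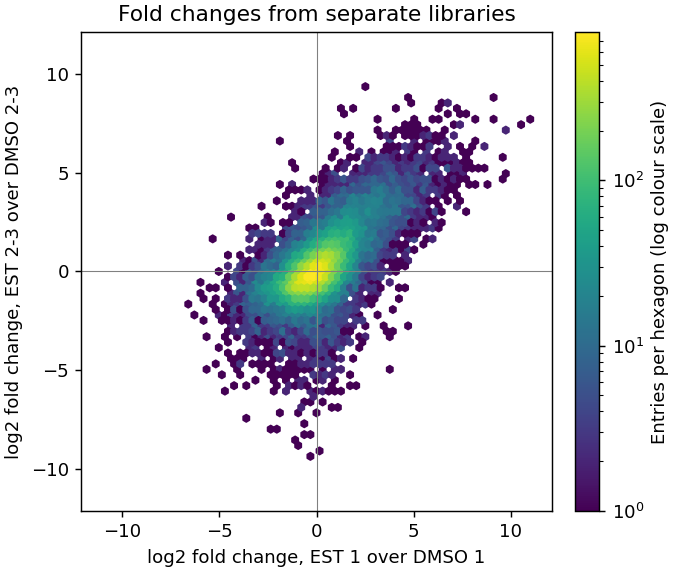
Log2 fold change of each tested gene model in EST 1 over DMSO 1 (x axis) and in EST 2 and 3 over DMSO 2 and 3 (y axis), with the number of gene models per hexagon on a log colour scale. The cloud runs along the diagonal, with a Pearson's r of 0.65 across gene models.

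The size of the transcriptome difference did not run in the order of the AtPIN5 level. Relative to the DMSO mean, 14493 gene models differed by over 2-fold in EST 1, 10302 in EST 2 and 8269 in EST 3, whereas AtPIN5 was lowest in EST 1 and highest in EST 3. With 1 library at each level, this order was not tested. EST 1 is also the only induced library from Novogene and the one with the fewest reads, so the order does not decide on an AtPIN5 dose.

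The EST libraries of the 2 companies were then compared. At an adjusted p under 0.05 in edgeR's quasi-likelihood test, 1410 gene models differed, 517 higher and 893 lower in the IAB libraries EST 2 and 3 than in EST 1. Of these, 830 were also called for treatment in the company-adjusted fit, 814 of them with the opposite sign. EST 1 enters both contrasts with opposite signs, so opposite directions are favoured by construction. The count was 0 without EST 2 (7958 at an unadjusted p under 0.05) and 0 without EST 3 (7000), 8568 without DMSO 1, 405 without DMSO 2 and 442 without DMSO 3. DESeq2 called 4084 on all 6 libraries.

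The DMSO libraries were unequally spaced. Between DMSO 2 and DMSO 3 the biological coefficient of variation was 0.0458, against 0.347 between DMSO 1 and 2, 0.355 between DMSO 1 and 3 and 0.280 between EST 2 and 3. Over 3880 gene models with whole-number estimates and at least 20 counts in the pair, the variance between DMSO 2 and 3 was 1.72 times that of sampling noise (chi-square test, p = 1.21e-152). By the same rule it was 8.71 times for EST 2 and 3 (4531 gene models), and 7.96 times for DMSO 1 and 2 (4193 gene models). Principal component 1 (64.1% of the variance) separated the groups, with DMSO 2 and 3 at −146 and −145, DMSO 1 at −53.3, EST 3 at 73.1, EST 2 at 110 and EST 1 at 162. Among the 2304 gene models that rose in both fits, DMSO 1 lay above the mean of DMSO 2 and 3 for 81.3%, and among the 749 that fell it lay below for 73.8%. These gene models were chosen from the same DMSO libraries, where DMSO 2 and 3 together outweigh DMSO 1. That choice favours such positions of DMSO 1, and no share over all tested gene models is given, so the shares do not measure a shift.

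**Figure D4:**
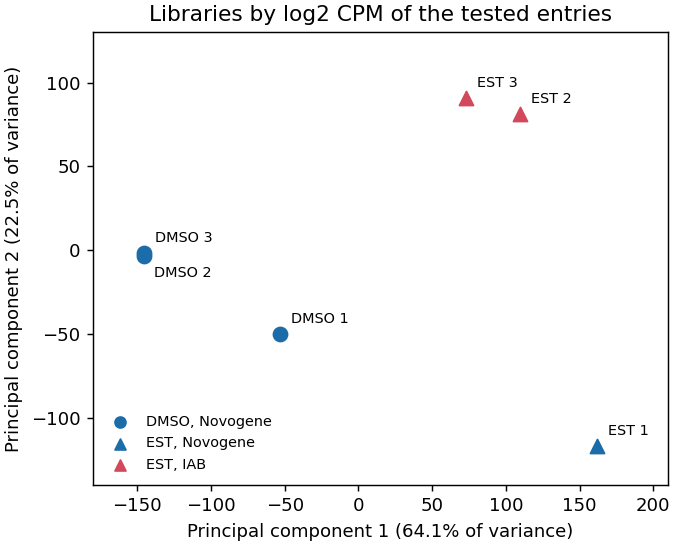
The 6 libraries on principal components 1 and 2 of log2 CPM over the tested gene models, circles DMSO and triangles EST, coloured by sequencing company. DMSO 2 and 3 nearly coincide at −146 and −145 on component 1, and DMSO 1 lies at −53.3, between them and the EST libraries.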

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

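The tests of explanations below, removal of the length trend included, were chosen after the data were seen. The EST libraries of the 2 companies differed in 1410 gene models by edgeR's quasi-likelihood test, a difference of the induced level between companies within the same treatment. EST 1 is the only Novogene library among them, and the count did not hold without EST 2 or without EST 3. Read coverage that depends on transcript length does not account for it, since 1781 gene models were called once each library's length trend was removed. By their labels, 0 replicates were sequenced by both companies, so a company difference cannot be told apart from a difference of culture or date between EST 1 and EST 2 and 3. The libraries themselves also differed by company. For entries of 1000 to 1500 bases, the median length minus effective length was 255 and 256 bases in EST 2 and 3. It was 398 in EST 1 and 380, 430 and 435 in DMSO 1, 2 and 3. With the effective lengths as an offset, 2172 gene models were called for company.

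DMSO 1 lay part of the way from DMSO 2 and 3 toward the induced libraries. Across gene models the SD of its log2 difference from EST 1 was 0.758 times that of DMSO 2, and 0.763 times once the length trend was removed, which argues against the company, as all these libraries are from Novogene, and against transcript length as the whole cause. Reads or RNA of EST 1 mixed into DMSO 1 would carry its abundant transcripts along, but over 25 gene models at 0 in DMSO 2 and 3 and at least 20 CPM in EST 1, DMSO 1 held a median of 0.412% of the EST 1 level (upper quartile 0.868%). The ratio was 0.824 for EST 2 and 0.855 for EST 3, but DMSO 2 and 3 nearly coincide, so a batch or culture shared by them, or in part one shared by DMSO 1 and EST 1, cannot be told apart from a culture state of DMSO 1. Leaky AtPIN5 stays open: DMSO 1 held the most of the controls (1.51 TPM, 29 reads), and DMSO 3 held 2.43 times the level of DMSO 2, which it nearly coincides with, but from 14 and 5 reads (counting interval 0.826 to 8.60), too few to decide; an AtPIN5 dose was not decided either, since EST 3, with more AtPIN5 mRNA than EST 2, followed the EST 1 response with 0.838 times its slope, but each level is 1 library.

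DMSO 2 and 3 differed far less than other replicates. They varied at 1.72 times sampling noise, and at 1.64, 1.88 and 1.37 times it in 3 classes of rising read count (the highest of 15 gene models), against 4.19, 13.1 and 87.1 for EST 2 and 3; since the noise between runs is not known here, 1 library sequenced in 2 runs cannot be told apart from separate libraries. Their biological coefficient of variation was 0.164 times the smaller of those of EST 2 and 3 and of DMSO 1 and 2, which is consistent with 2 libraries made from 1 culture or 1 RNA. The labels call them separate biological replicates, so this stays a hypothesis.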

How the results depend on the processing

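DMSO 2 and 3 summed, the 3 library pairs as batch, whole-number estimates only and the length trend were chosen after seeing the data. The pooled and both-fit calls of edgeR rest on DMSO 2 and 3 counting as 2 libraries: summed, the company-adjusted, pooled, both-fit and company counts were 2791, 1, 1 and 402 (DESeq2 on the summed libraries gave 5698, 3894, 2582 and 2451), and pooled AtPIN5 fell short of the threshold (log2 7.23, adjusted p = 0.0729). The fewer libraries leave fewer degrees of freedom. The same loss of 1 library, however, left 4146 pooled calls without DMSO 1, 6771 without EST 1, 3534 without EST 3 and 792 without EST 2. It left 0 without DMSO 2 and 1 without DMSO 3. These counts argue against fewer degrees of freedom as the whole cause of the pooled loss. The near-complete loss came only where DMSO 2 and 3 no longer counted as 2 libraries, and no further cause was tested. Leaving out 1 library gave ranges of 2652 to 16467, 0 to 6771, 0 to 4121 and 0 to 8568 for the 4 counts, and of 6.09 to 8.09 for pooled log2 AtPIN5. Restriction to the 5048 entries with whole-number estimates gave 1242, 792, 629 and 259, as fewer entries were tested. For the other moved counts the cause was not tested. A filter of 10 counts in every library gave 2188 pooled, 1740 in both fits and 825 for company, and DESeq2 gave 7107, 4908 and 4084. The company count was 3057 without a filter, 3040 with limma and 2172 with the length offset. The replicate block gave 7566 pooled, 6127 company-adjusted and 3652 in both fits, and changed no other call. Of the 4 counts, the company-adjusted one stayed within 1.5 times its value in 12 of 19 alternatives. Of these 12, the Novogene libraries alone (6054) repeat the contrast of EST 1 with the DMSO libraries, with the spread from DMSO only, and the 3 library pairs as batch (5729) and the replicate block compare EST 1 with DMSO 1 alone, with the spread from other libraries, so these 3 say nothing on stability. Its balance turned to 4064 higher and 4357 lower under upper-quartile scaling and to 2792 and 2937 with the library pairs as batch, and the higher share rose from 54.3% to 71.6% and 71.8% without DMSO 2 and without DMSO 3. None of the 132 values of the 4 named gene models reversed, and 20 lost the threshold, all in the pooled fit. AtPIN5 in the company-adjusted fit ran from 3.72 to 5.55 (adjusted p 2.32e-09 to 0.04995). Without EST 1 no company term could be fitted. AtPIN5 drops out under the filter of 10 counts in every library and under whole-number estimates. Gene list tests and sums over transcripts were not run, because no names pair with the identifiers and each gene model has 1 entry. At the depth of these libraries, 2-fold changes in simulated counts were recovered in 1.49% of cases by the company-adjusted and 14.9% by the pooled fit. The simulated libraries varied independently, unlike DMSO 2 and 3, so these rates may not hold for the data. Small changes can go uncalled, and depth was not varied.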

Other observations

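Tests of neighbouring gene models were chosen after seeing neighbours among the largest rises in the data, as was the restriction to whole-number estimates. Gene models with adjacent numbers on the same scaffold, as their identifiers give it, might respond together. Of 16570 adjacent tested pairs, 91 had both members among the 2304 that rose in both fits, within the 42 to 107 of 10000 random placements of the calls (one-sided permutation p = 0.0506). With both members at whole-number estimates, the observed number was 1.45 times the random mean, on 7 pairs, too few to weigh reads shared between copies. Among the 749 that fell, 21 pairs were 2.60 times the random mean of 8.08 (one-sided permutation p = 2.00e-04). They reach but do not exceed the upper end of the random range of 0 to 21. Whole-number estimates were checked for the rises only, so reads shared between copies stay open as a cause for the falls.

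The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 8351, 3770 and 3053 gene models in the company-adjusted fit, the pooled fit and both, and was the 1 division of the 10 with as many. The highest count of any other division was 0 in each, the 3 others that also part every replicate number included. Every other division puts the difference between EST and DMSO libraries into the spread. All except DMSO 1, EST 2 and EST 3 against the rest also part DMSO 2 from 3 or EST 2 from 3. Counts near 0 were therefore favoured by construction, and the contrast with the real division is no evidence of a response.

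Effective-length profiles of the libraries, relative to their mean, correlated within DMSO 1 and EST 1 (r = 0.43), DMSO 2 and 3 (r = 0.74) and EST 2 and 3 (r = 0.70), and at or under −0.16 for every other combination, across entries of 600 to 4000 bases. The 3 groupings are those of the library identifiers. Because each profile is taken relative to the mean of all libraries, positive values within groupings favour negative ones between them by construction.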
